A study of Rattus norvegicus with 40 samples.

How the data were processed

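Total RNA from cultured neonatal rat ventricular heart muscle cells was measured on 40 Affymetrix rat genome arrays. Ischemia was produced in culture by coverslip hypoxia, per the labels, a model in which a coverslip laid over the cells restricts their supply of oxygen and medium. The labels divide the arrays into 10 groups, ischemia alone or ischemia followed by reperfusion, each at 0, 10, 30, 60 and 120 min. Every group held 4 arrays, 2 duplicates from each of 2 cell preparations. The labels do not say whether the duplicates were separate cultures or repeat arrays of the same RNA, how long reperfusion lasted, or which part of the protocol the minutes cover. The duplicates were averaged in the main fit, so its p-values measure the spread of these averages about the group and preparation effects. Nothing says that the duplicates were separate cultures, so part of that spread may be technical. Where arrays were taken as samples, p-values also measure the spread between duplicates, which may be technical.

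The deposited values were probe set intensities on a linear scale, from -1725 to 17404, and 15.8% of them were negative, so a background or mismatch signal had been subtracted. RNA was extracted on spin columns and biotin-labelled cRNA was made by an Eberwine-type amplification, per the labels' protocols. The algorithm that made the probe set values and its scaling are not given in the sources used here. The deposited intensity medians of the arrays ran from 101 to 171, so the arrays were not on a common scale.

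The table held 31042 probe sets and no control probe sets. Of these, 20826 carried 1 gene symbol (14217 genes), 436 carried several and 9780 were unnamed in the annotation used here. Genes were named only from probe sets with 1 symbol, and no genome was used. Values were quantile-normalized between the 40 arrays, set to a floor of 0 where negative, and transformed as log2(value + 16), so fold changes are on that scale and understate the change of dim probe sets. Probe sets with a mean log2 value above the 40th percentile (6.48, an intensity of 73.2) were tested, which left 18625 probe sets, 14311 of them with 1 symbol (10483 genes). Of the tested values, 0.07% lay at the floor. The duplicates of a group and preparation were averaged, which gave 20 values and n = 2 preparations per group.

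The tests, gene lists, naming rule and alternatives were fixed before the data were examined, with exceptions given here. The rule for the scale would have kept the deposited scale, because the array medians spanned 0.68 log2 units and the limit was 1. Quantile normalization was used all the same, because unscaled array medians shift whole comparisons: the median change of all probe sets in a comparison ran from -0.23 to 0.21 log2 units on the deposited scale and from -0.02 to 0.02 on the normalized scale. Counts on the deposited scale are printed beside the main ones where they differ. Removal of single doubted arrays, and a comparison of 120 with 10 min of ischemia, were added after the values were seen.

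All 10 groups were fitted in a single linear model with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with the preparation as an additive block. The fit had 9 residual degrees of freedom and a prior of 2.27. Moderated two-sided tests were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 counted as a call. Each duration was compared with 0 min within its arm, ischemia+reperfusion with ischemia at each duration, and the interaction was tested at 120 min and by a moderated F test over the 4 interaction terms. The median standard error of a comparison was 0.118 log2 units, with a 95% interval half-width of 0.258, and the number of arrays limits this precision. On simulated data with the layout of the 120 against 0 min ischemia comparison (18625 probe sets), the fit recovered 37.3% of changes of 0.5 log2 units, 77.6% of changes of 1 and 98.5% of changes of 2, with 3 false calls. The simulated noise was independent between probe sets and held no deviating array, so these rates need not hold for the measured arrays.

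The block rests on the labels, which mark a preparation shared by all groups. The preparation differences of the groups correlated by a median of 0.18 (-0.18 to 0.53), above 0.1 in 34 of 45 pairs of groups. The correlation of duplicates within a group and preparation, estimated by duplicateCorrelation, was 0.08. No pair of arrays held identical values.

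The gene lists numbered 23, with 518 genes, of which 477 were on the array and 441 were tested; the erythroid list had 0 tested members and gave no result. The brightest probe set stood for each gene. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data. Members were counted as called over all probe sets tested and as adjusted over the list alone. Genes are named by rule: in the comparisons of 120 with 0 min in each arm and of the arms at 0 and 120 min, the 10 largest rises and 10 largest falls among calls with the same sign in both preparations; elsewhere the 3 largest of each; up to 4 called members of each list, or the 2 with the smallest p where none passed; and a panel of 10 genes followed through all groups, of which Gapdh was left out because its probe set carries several symbols. The text prints a selection of these. Genes named outside this rule are marked as chosen after their values were seen.

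Alternatives were no block, arrays as separate samples with and without a duplicate correlation, no filter and a filter at the 60th percentile, no normalization and median centring, pseudocounts of 1 and 64, 1 probe set per gene, each preparation alone, and removal of each array or preparation in turn. Lists were also tested with limma's fry. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.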

Results

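Gene expression was measured on 40 arrays from neonatal rat ventricular heart muscle cells exposed to ischemia, or to ischemia followed by reperfusion, for labelled times of 0, 10, 30, 60 and 120 min. Each of the 10 groups held 4 arrays from 2 cell preparations. Log2 changes are given with their standard error (SE) from limma, with n = 2 preparations per group, and adjusted p-values are over the 18625 probe sets tested in a comparison. Fold changes against 0 min give the change with labelled time within an arm. Comparisons between the arms at equal time give the difference of the arms. They do not isolate reperfusion, because 62 probe sets already differed between the arms at 0 min.

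By the correlation of their centred values, 16 of the 40 arrays lay nearest to another group than the one on their label, 4 of them by a gap of over 0.1. At 120 min, the ischemia array of preparation 2, duplicate 2, had a log2 value of 13.15 for Hspa1a, the inducible heat shock protein 70, where the other 3 arrays of its group had 9.62 to 10.19. The ischemia+reperfusion array of preparation 2, duplicate 1, had 9.75, where the other 3 had 13 to 13.25. The 10 min ischemia+reperfusion array of preparation 2, duplicate 1, lay with the 0 min arrays of its arm (correlation 0.31, against 0.08 with its own group). The fourth, the 30 min ischemia+reperfusion array of preparation 2, duplicate 1, lay nearer to the 60 min group of its arm (0.22) than to its own (0.07), and all 4 arrays of that 30 min group lay nearer to another group. Without it, 167 probe sets passed at 30 min of ischemia+reperfusion, against 146 with it. A further array, of 0 min ischemia (preparation 1, duplicate 1), had a median correlation of 0.872 with the other arrays, against 0.960 to 0.979 for the rest. All arrays were kept under their labels, and counts without these arrays are printed where they differ.

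**Figure D1:**
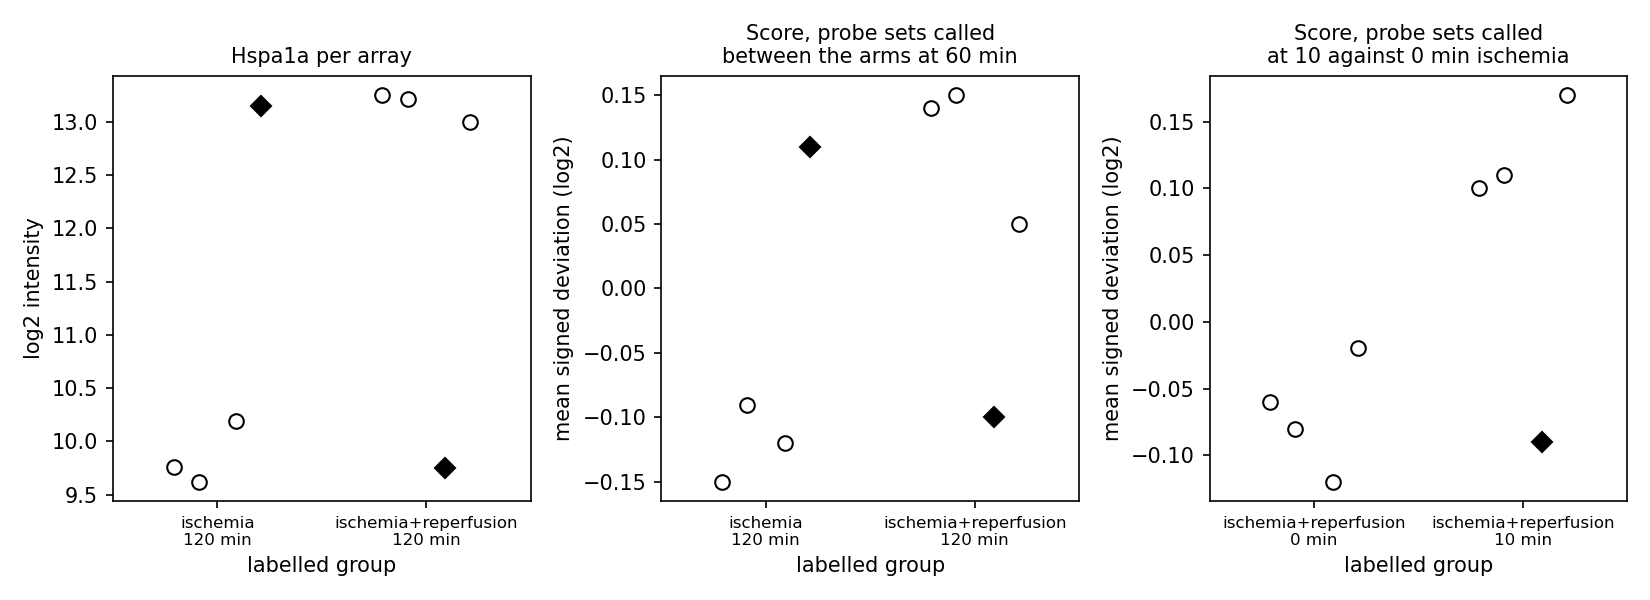
Values per array in the labelled groups. The left panel gives the log2 intensity of Hspa1a at 120 min, and the middle and right panels give the mean deviation, signed by the direction of the call, over the 1002 probe sets called between the arms at 60 min and the 368 called between 10 and 0 min of ischemia. Filled diamonds mark 3 of the 4 arrays that lie with another group: at 120 min the ischemia array scores 0.11 and the ischemia+reperfusion array -0.10, and the 10 min array scores -0.09.

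After 120 min of ischemia, some immediate early genes, targets of the hypoxia-inducible factor HIF and cytokines rose. Fos, an AP-1 transcription factor of the immediate early response, rose by 2.83 ± 0.20 log2 units (adjusted p = 0.00037), and the nuclear receptor Nr4a1 rose by 1.98 ± 0.19 (adjusted p = 0.00071). The chemokine Cxcl2 rose by 2.93 ± 0.24 (adjusted p = 0.00047) and the cytokine Il1b by 2.17 ± 0.19 (adjusted p = 0.00048). Among HIF targets, Ankrd37 rose by 3.20 ± 0.38 (adjusted p = 0.0021) and Ddit4, an inhibitor of mTORC1 signalling, by 2.50 ± 0.27 (adjusted p = 0.0012). Ak4, a mitochondrial adenylate kinase, had the largest rise, 4 ± 0.65, but 3 of the 4 arrays at 0 min were at the floor for it and its adjusted p of 0.0065 became 0.094 without the outlying 0 min array. Hilpda, which coats lipid droplets in hypoxia, rose by 2.17, and Rrad, a small GTPase, by 2.25. The largest falls included Synpo, an actin-binding protein (-2.37), Gnaq, a G protein subunit that couples to phospholipase C (-1.98 ± 0.36), and Etnk1, an ethanolamine kinase (-1.89 ± 0.29). Egfl7, an endothelial secreted factor, fell by 2.35 on a probe set of its own, while another tested probe set of the gene was not called.

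Of 31 immediate early genes measured, 14 rose, 0 fell and 17 did not pass (18 rose and 1 fell when adjusted over the list alone). The list's median change was 0.71, with a camera adjusted p of 1.11e-08 and an adjusted p of 0.443 with an estimated correlation. Atf3 (1.79 ± 0.43) and Sik1, a salt-inducible kinase (2.19 ± 0.35), were among its members. Of 32 HIF targets, 14 rose, 0 fell and 18 did not pass (20 rose when adjusted over the list alone). Their median was 0.70, with a camera adjusted p of 1.87e-09 and an adjusted p of 0.475 with an estimated correlation. Pfkfb3, which makes the main activator of phosphofructokinase, rose by 1.69 ± 0.23, and Vegfa, the vascular growth factor, by 0.73 ± 0.16. Of 25 inflammatory and NF-kB genes, 9 rose, 0 fell and 16 did not pass (14 rose when adjusted over the list alone). Their median was 0.40, with a camera adjusted p of 1.91e-07 and an adjusted p of 0.443 with an estimated correlation. Il1a was called on both of its probe sets (2.58 ± 0.47 and 1.68 ± 0.15). Beside these, 0 of 13 macrophage and leukocyte markers passed in the limma test, and their median change was 0.18, from -0.15 to 0.40. Tyrobp, the macrophage marker with the smallest p, changed by 0.35 (adjusted p = 0.12).

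Of 21 NRF2 and antioxidant genes, 4 rose, 0 fell and 17 did not pass (5 rose and 1 fell when adjusted over the list alone). Their median was 0.19, with a camera adjusted p of 0.0208 and an adjusted p of 0.503 with an estimated correlation. They included Hmox1, which degrades heme (1.93 ± 0.32), and the metallothionein Mt2A (1.64 ± 0.36). Of 9 endothelial markers, 5 rose, 0 fell and 4 did not pass (7 rose when adjusted over the list alone). Their median was 0.42, with a camera adjusted p of 0.000739 and an adjusted p of 0.461 with an estimated correlation. Pecam1, an endothelial adhesion molecule, rose by 1.04 ± 0.24 (adjusted p = 0.021, or 0.13 without the block). Of 20 fibroblast markers, 5 rose, 0 fell and 15 did not pass (7 rose when adjusted over the list alone). Their median was 0.14, with a camera adjusted p of 0.00812, or 0.0605 on the deposited scale, and an adjusted p of 0.533 with an estimated correlation. Of 40 oxidative phosphorylation genes, Ndufs1 (-0.28 ± 0.06, adjusted p = 0.017, or 0.083 without the block) and Uqcrc2 (-0.24 ± 0.06) fell, 0 rose and 38 did not pass (the same numbers when adjusted over the list alone). The median of that list was -0.04, with a camera adjusted p of 0.00248 and an adjusted p of 0.533 with an estimated correlation.

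In all, 2408 of 18625 probe sets passed at 120 min of ischemia, 1202 higher and 1206 lower (1653 genes), with 170 higher and 86 lower by at least 1 log2 unit. The count was 1484 without the preparation as a block and 3036 without the pair of arrays out of place at 120 min. On the deposited scale, where the median change lay 0.22 lower at -0.22, 3414 probe sets passed, 271 higher and 3143 lower. An unlabelled batch of arrays or RNA, described below, could enter this comparison and cannot be told apart from duration.

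**Figure D2:**
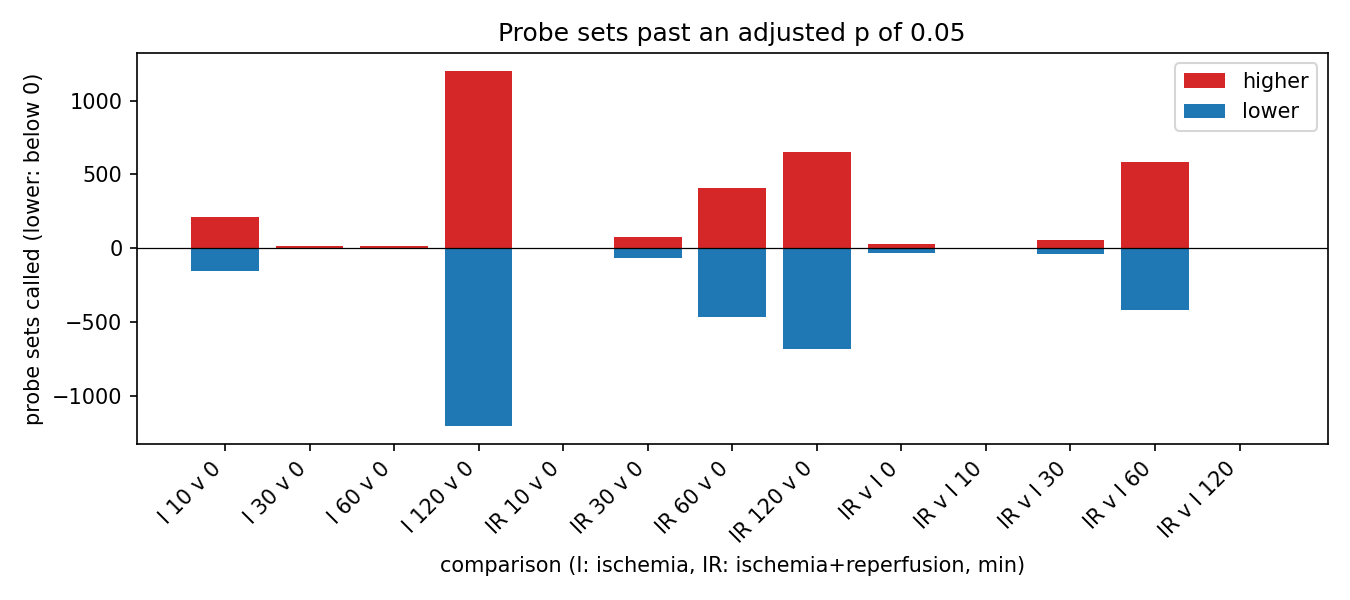
Number of probe sets past an adjusted p of 0.05 (vertical axis; higher drawn above 0, lower below) in 13 comparisons. I is ischemia and IR is ischemia+reperfusion, and v marks the group compared against. The tallest bars belong to 120 min of ischemia, with 1202 probe sets higher and 1206 lower.

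At 10 min of ischemia, the medians of HIF targets and glycolytic enzymes lay above 0 and passed in camera at the preset correlation, but not with an estimated one. Immediate early genes had a median change of 0.07. Of 32 HIF targets, 5 rose, 0 fell and 27 did not pass (25 rose when adjusted over the list alone). Their median was 0.67, with a camera adjusted p of 4.49e-14 and an adjusted p of 0.761 with an estimated correlation. Of 18 glycolytic enzymes, 1 rose, 0 fell and 17 did not pass (10 rose when adjusted over the list alone). Their median was 0.24, with a camera adjusted p of 2.88e-06 and an adjusted p of 0.761 with an estimated correlation. Without the outlying array, 2 of the HIF targets and 0 of the glycolytic enzymes passed in limma over all probe sets. Aspdh, annotated as an aspartate dehydrogenase, rose by 2.55 (adjusted p = 0.022, or 0.051 without the block) and Ina, a neuronal intermediate filament, by 2.39. Among the falls were Rlim, a ubiquitin ligase (-1.59), Atrx, a chromatin remodeller (-1.57), and Prpf38b, a splicing factor (-1.48). In all, 368 probe sets passed, 212 higher and 156 lower, with 176 without the preparation block, 251 without the outlying array and 66 (42 higher, 24 lower) on the deposited scale. Leaving out the 0 min array of preparation 2, duplicate 1, gave 660 calls, and leaving out the 10 min arrays of preparation 2 gave 639 (duplicate 1) and 160 (duplicate 2).

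By 30 and 60 min of ischemia, Fos rose. Fos was 2.28 ± 0.20 log2 units above 0 min at 30 min (adjusted p = 0.0018) and 2.78 ± 0.20 above it at 60 min (adjusted p = 0.00045). Cxcl2 rose by 1.66 ± 0.24 at 60 min (adjusted p = 0.029, or 0.08 without the block). Uox, the urate oxidase gene, changed by -2.65 at 30 min and -3.36 at 60 min, with 3 of the 4 arrays of either group at the floor, and the 30 min call was lost without the outlying array (adjusted p = 0.08). At 30 min, 1 of 31 immediate early genes rose, 0 fell and 30 did not pass (7 rose when adjusted over the list alone), with a camera adjusted p of 8.65e-07 and an adjusted p of 0.368 with an estimated correlation. At 60 min, 4 rose, 0 fell and 27 did not pass (14 rose when adjusted over the list alone), with a camera adjusted p of 3.93e-10 and an adjusted p of 0.418 with an estimated correlation.

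HIF targets kept a positive median, 0.60 at 30 min and 0.53 at 60 min, although 0 of 32 passed over all probe sets with limma at either time (24 and 23 rose when adjusted over the list alone). Their camera adjusted p was 3.21e-17 at 30 min, with an adjusted p of 0.368 with an estimated correlation, and 2.34e-16 at 60 min, with an adjusted p of 0.418 with an estimated correlation. Sterol synthesis and SREBP target genes had medians of -0.14, -0.27 and -0.19 at 10, 30 and 60 min of ischemia, with 1, 0 and 0 of 19 past limma's threshold (7, 9 and 6 fell when adjusted over the list alone). Their camera adjusted p was 0.000152, 7.01e-08 and 3.85e-05, with an adjusted p of 0.761, 0.368 and 0.418 with an estimated correlation. At 120 min, in the fit without the pair of arrays out of place, 1 of the 19 rose and 1 fell. Their median was then -0.16, with a camera adjusted p of 0.167. In all, 18 probe sets passed at 30 min, 13 higher and 5 lower, against 2911 at an unadjusted p under 0.05, and 24 passed at 60 min, 16 higher and 8 lower, against 2937. The 60 min count was 14 without the preparation block and 17 without the outlying array. At 30 min, the count fell to 2 without the outlying 0 min array, and it was 68 without the 0 min array of preparation 2, duplicate 2, and 44 without the 30 min array of preparation 1, duplicate 1. At 60 min it was 46 without the 0 min array of preparation 2, duplicate 2, and 14 and 37 without the 60 min arrays of preparation 1, duplicate 1, and preparation 2, duplicate 1. On the deposited scale, where the median change lay at -0.23 and -0.17, 4 probe sets were higher and 12 lower at 30 min, and 1 was higher and 2 lower at 60 min.

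In the ischemia+reperfusion arm, Hspa1a and some immediate early and cytokine genes rose at 120 min, and some sterol synthesis genes fell. Hspa1a rose by 3.15 ± 0.59 log2 units (adjusted p = 0.015). Atf3, a stress-induced transcription factor, rose by 3.05 ± 0.43 (adjusted p = 0.0063), Fos by 2.37 ± 0.20 (adjusted p = 0.0018) and the nuclear receptor Nr4a3 by 2.54 ± 0.34 (adjusted p = 0.0047). On the brightest probe set of Nr4a3 the rise was 1.03 (adjusted p = 0.035). Cxcl2 rose by 2.45 ± 0.24 (adjusted p = 0.0019), Il1b by 2.00 ± 0.19 (adjusted p = 0.0019) and Ptgs2, the inducible cyclooxygenase, by 1.48 ± 0.15 (adjusted p = 0.0021). Klhl40, a muscle protein that stabilises thin filaments, rose by 2.61, and Mgarp, a mitochondrial protein, by 4.22 ± 1.13 (adjusted p = 0.048, or 0.054 without the block), with all 4 arrays at 0 min at the floor. The largest falls included Ap3d1, an adaptor subunit of vesicle traffic (-1.86), Nek9, a mitotic kinase (-1.85), Gnaq (-1.56, adjusted p = 0.03, or 0.055 without the block), Clu, a secreted chaperone (-1.48, adjusted p = 0.024, or 0.14 without the block), and Lrrc10, a cardiac sarcomere protein (-1.20).

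Of 31 immediate early genes, 13 rose, 0 fell and 18 did not pass (22 rose and 1 fell when adjusted over the list alone). Their median was 0.62, with a camera adjusted p of 1.55e-13 and an adjusted p of 0.108 with an estimated correlation. Egr1, a zinc finger transcription factor, rose by 1.18 ± 0.14. Of 32 HIF targets, 13 rose, 0 fell and 19 did not pass (23 rose when adjusted over the list alone). Their median was 0.67, with a camera adjusted p of 5.18e-15 and an adjusted p of 0.235 with an estimated correlation. Of 25 inflammatory and NF-kB genes, 10 rose, 0 fell and 15 did not pass (14 rose when adjusted over the list alone). Their median was 0.35, with a camera adjusted p of 1.34e-09 and an adjusted p of 0.108 with an estimated correlation. Beside them, Mrc1 was the only macrophage and leukocyte marker of 13 to pass, falling (-0.69, adjusted p = 0.029, or 0.2 without the block), and the markers had a median of 0.09, from -0.69 to 0.59. Of 21 NRF2 and antioxidant genes, 4 rose, 1 fell and 16 did not pass (9 rose and 2 fell when adjusted over the list alone). Their median was 0.16, with a camera adjusted p of 0.00312 and an adjusted p of 0.329 with an estimated correlation. Hmox1 rose by 1.79 ± 0.32.

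Of 19 sterol synthesis and SREBP target genes, 0 rose, 10 fell and 9 did not pass (15 fell when adjusted over the list alone). Their median was -0.47, with a camera adjusted p of 1.12e-11 and an adjusted p of 0.108 with an estimated correlation. Mvd, which makes isopentenyl pyrophosphate, fell by 0.97 ± 0.16, Idi1, which isomerises that product, by 0.78 ± 0.14, and Sqle, the squalene epoxidase, by 0.63 ± 0.08. Without the preparation block, Mvd kept its call, while Idi1 (adjusted p = 0.065) and Sqle (adjusted p = 0.088) did not. Of 21 heat shock proteins and co-chaperones, Hspa1a and Hspa4l (0.58 ± 0.14) rose, 0 fell and 19 did not pass (3 rose when adjusted over the list alone). The median of that list was 0.09, with a camera adjusted p of 0.00648 and an adjusted p of 0.382 with an estimated correlation. Without the pair of arrays out of place at 120 min, 8 of the 21 rose, with a camera adjusted p of 2.47e-06 and an adjusted p of 0.0419 with an estimated correlation. Hspa1a, which showed the pair to be out of place, is a member of the list, so these values are not a test of it.

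In all, 1336 probe sets passed at 120 min of ischemia+reperfusion, 651 higher and 685 lower, with 645 without the preparation block. The count was 305 on the deposited scale (138 higher and 167 lower, where the median change lay at -0.12), and with each array centred on its median it was 1551, 451 higher and 1100 lower. The 120 min comparisons of the arms shared no array, but they shared the preparations and the variance estimate of each probe set. Their lists were therefore not independent, and the counts for independent lists given here may be too low. Of the calls, 310 probe sets were higher in both, against 42 for independent lists, and 296 were lower in both, against 44.4. An exchange between the pair out of place could raise this overlap. Without the pair, 293 were higher in both, against 58.1, and 218 lower, against 54, with 9 and 17 called in opposite directions (5 and 2 as labelled).

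**Figure D3:**
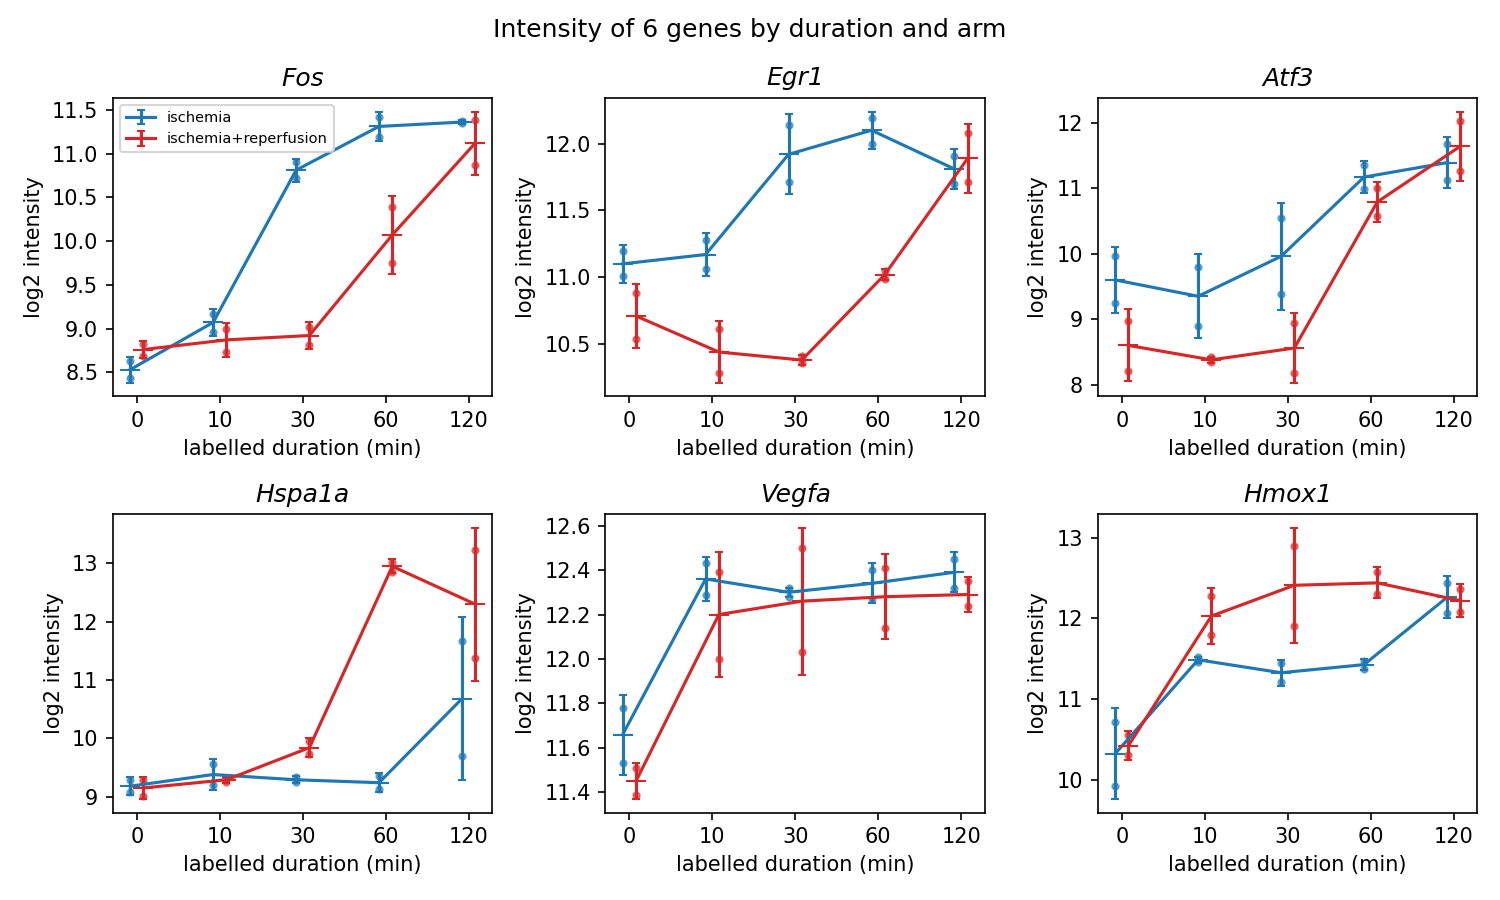
Log2 intensity (vertical axis) of Fos, Egr1, Atf3, Hspa1a, Vegfa and Hmox1 at 5 labelled durations (horizontal axis, min, evenly spaced) in each arm. Points are the 2 preparations, horizontal marks their mean and bars the SD (n = 2). Fos reached 10.81 at 30 min in ischemia and 8.92 in ischemia+reperfusion, and Hspa1a stood at 9.24 and 12.95 at 60 min; the wide bars of Hspa1a at 120 min come from the pair of arrays out of place.

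At the shorter times of ischemia+reperfusion, the median of the sterol synthesis genes lay below 0 and passed in camera at the preset correlation, but not with an estimated one. At 10 min, Fdft1, the squalene synthase (-0.69 ± 0.09), Cyp51, a lanosterol demethylase (-0.68), and Dhcr7, a late step of cholesterol synthesis (-0.64), were called. These calls were lost without the preparation block (adjusted p = 0.49, 0.23 and 0.47) and without the outlying array (adjusted p = 0.065, 0.10 and 0.065). Over the representatives of 19 sterol genes, 0 rose, 2 fell and 17 did not pass (17 fell when adjusted over the list alone). Without the outlying array 0 fell, and without the 10 min array that lay with 0 min 9 fell. The list's median was -0.43, with a camera adjusted p of 1.04e-18 and an adjusted p of 0.0829 with an estimated correlation. The HIF targets had a median of 0.64 at 10 min, with 0 of 32 past limma's threshold over all probe sets (26 rose when adjusted over the list alone), a camera adjusted p of 5.81e-27 and an adjusted p of 0.142 with an estimated correlation. Mapt, the tau protein, rose by 2.94. In all, 7 probe sets passed at 10 min, 4 higher and 3 lower, against 2101 at an unadjusted p under 0.05.

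Without the 10 min array of preparation 2, duplicate 1, which lay with the 0 min arrays, 348 probe sets passed at 10 min of ischemia+reperfusion, 219 higher and 129 lower, and 19 of 32 HIF targets rose, among them Ankrd37 by 2.79 ± 0.32 (adjusted p = 0.0026, or 0.054 as labelled). Hmox1 rose by 1.99 ± 0.31 in that fit (adjusted p = 0.013, or 0.084 as labelled). The HIF list had an adjusted p of 0.101 with an estimated correlation there. Leaving out an array for lying with 0 min favours a difference from 0 min, so these p-values are not those of a planned test. The 7 calls became 2 without the preparation block, 1 without the outlying array, 29 (28 higher, 1 lower) on the deposited scale, where the median change lay at 0.10, and 3, all higher, with median centring. Leaving out the 0 min arrays gave 50 (preparation 1, duplicate 1), 2 (preparation 1, duplicate 2), 16 (preparation 2, duplicate 1) and 37 calls (preparation 2, duplicate 2), and leaving out the 10 min array of preparation 2, duplicate 2, gave 1.

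At 30 min of ischemia+reperfusion, Klhl40 rose by 2.81 (adjusted p = 0.038, or 0.071 without the block) and Ankrd37 by 2.45 ± 0.38 (adjusted p = 0.018), while Lrrc10 fell by 1.42. The arrestin-related genes Arrdc4 and Txnip, which restrain glucose uptake, fell by 1.41 (adjusted p = 0.02) and 1.08 (adjusted p = 0.048), and both calls were lost without the block (adjusted p = 0.071 and 0.23). Of 19 sterol genes, 0 rose, 7 fell and 12 did not pass (18 fell when adjusted over the list alone). Their median was -0.53, with a camera adjusted p of 3.49e-19 and an adjusted p of 0.0768 with an estimated correlation. Of 32 HIF targets, 4 rose, 0 fell and 28 did not pass (24 rose when adjusted over the list alone). Their median was 0.73, with a camera adjusted p of 6.49e-23 and an adjusted p of 0.237 with an estimated correlation. In all, 146 probe sets passed, 76 higher and 70 lower, with 56 without the preparation block and 65 (28 higher, 37 lower) on the deposited scale.

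At 60 min of ischemia+reperfusion, Hspa1a rose by 3.80 ± 0.59 (adjusted p = 0.0096), Klhl40 by 3.45 and Nr4a3 by 2.28, while Gsg1, a germ cell protein (-2.88), Dtx4, a regulator of Notch signalling (-2.60, adjusted p = 0.024, or 0.1 without the block), and Prickle2, a planar polarity protein (-2.06), fell. Of 19 sterol genes, 0 rose, 11 fell and 8 did not pass (18 fell when adjusted over the list alone). Their median was -0.58, with a camera adjusted p of 2.09e-15 and an adjusted p of 0.139 with an estimated correlation. Of 32 HIF targets, 11 rose, 0 fell and 21 did not pass (23 rose when adjusted over the list alone), with a camera adjusted p of 2.17e-14 and an adjusted p of 0.383 with an estimated correlation. Of 31 immediate early genes, 8 rose, 0 fell and 23 did not pass (11 rose when adjusted over the list alone). Their median was 0.35, with a camera adjusted p of 2.14e-08 and an adjusted p of 0.383 with an estimated correlation. Of 21 heat shock proteins and co-chaperones, 3 rose, 0 fell and 18 did not pass (6 rose when adjusted over the list alone), with a camera adjusted p of 0.000308 and an adjusted p of 0.383 with an estimated correlation. In all, 873 probe sets passed, 407 higher and 466 lower, with 411 without the preparation block, 157 (91 higher, 66 lower) on the deposited scale, 1068 (269 higher, 799 lower) with median centring, and 1420 without the 60 min array of preparation 1, duplicate 2.

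**Figure D4:**
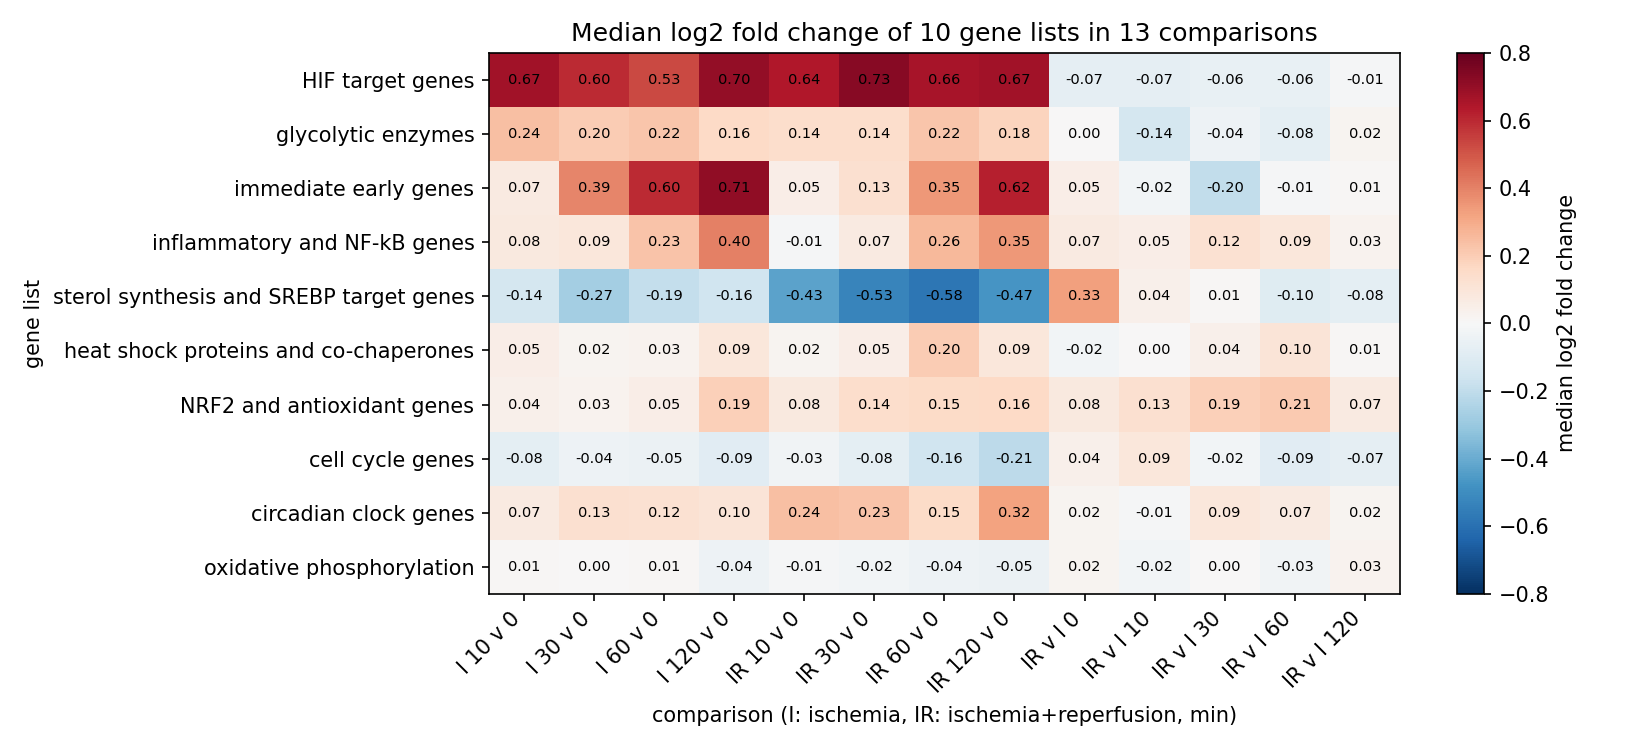
Median log2 fold change of the tested members of 10 gene lists (vertical axis) in 13 comparisons (horizontal axis; I is ischemia, IR is ischemia+reperfusion, v marks the group compared against). The number in each cell is the median, red above 0 and blue below 0. HIF targets lie between 0.53 and 0.73 in all 8 comparisons with 0 min, and the sterol genes lie between -0.58 and -0.43 in the ischemia+reperfusion arm.

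Between the arms at 0 min, where neither carried a labelled exposure time, a few genes differed. Lower in ischemia+reperfusion were Dennd4b, a Rab exchange factor (-2.33 ± 0.41, adjusted p = 0.048), Mapt (-2.29 ± 0.28, adjusted p = 0.011), Atrx (-1.53), Ankrd11, a chromatin regulator (-1.36), and H1f4, a linker histone (-1.23 ± 0.14, adjusted p = 0.0095). Higher were Rgs14, a regulator of G protein signalling (1.51), Car3, a carbonic anhydrase (1.15), Irf2, an interferon regulatory factor (0.74 ± 0.08, adjusted p = 0.0095), and Nfkbil1 (0.63 ± 0.06, adjusted p = 0.0095). Without the preparation block, Dennd4b (adjusted p = 0.099), Atrx (0.052), Ankrd11 (0.059), Rgs14 (0.059) and Car3 (0.079) lost their calls. Of 19 sterol genes, Sqle rose (0.47 ± 0.08, adjusted p = 0.048, or 0.29 without the block), 0 fell and 18 did not pass (9 rose when adjusted over the list alone, and 2 over all probe sets without the outlying array). Their median was 0.33, with a camera adjusted p of 6.10e-07 and an adjusted p of 0.466 with an estimated correlation. In all, 62 probe sets passed, 29 higher and 33 lower, with 16 without the block, 157 without the outlying array, and 17 (10 higher, 7 lower) on the deposited scale. Leaving out another ischemia array gave 28 (preparation 1, duplicate 2), 238 (preparation 2, duplicate 1) or 148 calls (preparation 2, duplicate 2), and leaving out the ischemia+reperfusion arrays of duplicate 1 gave 118 (preparation 1) and 114 (preparation 2).

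In ischemia+reperfusion against ischemia, Fos and Egr1 were lower at 30 and 60 min and Hspa1a was higher at 60 min. At 30 min, Fos was lower by 1.89 on the log2 scale (-1.89 ± 0.20, adjusted p = 0.0041) and Egr1 changed by -1.54 ± 0.14 (adjusted p = 0.0024). At 60 min, Fos changed by -1.24 ± 0.20 (adjusted p = 0.013) and Egr1 by -1.08 ± 0.14 (adjusted p = 0.0071), both chosen as members of the panel, while Hspa1a rose by 3.71 ± 0.59 (adjusted p = 0.011). Uox was higher at both times, by 2.71 and 3.54, although 3 of the 4 ischemia arrays were at the floor. Ankrd37 was higher at 30 min by 2.00 ± 0.38 (adjusted p = 0.048, or 0.051 without the block). Gsg1 (-3.36), Camk2g, a calcium-dependent kinase subunit (-2.84, adjusted p = 0.044, or 0.053 without the block), and Rnf126, a ubiquitin ligase (-2.75), were lower at 60 min. The interaction, which sets aside the difference of the arms at 0 min, gave 0 calls in limma at 30 and at 60 min. For Fos it was -2.12 at 30 min and -1.46 at 60 min (adjusted p = 0.12 and 0.23). For Egr1 it was -1.15 and -0.69 (adjusted p = 0.39 and 0.31), and for Hspa1a 3.74 at 60 min (adjusted p = 0.24).

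Of 31 immediate early genes at 30 min, 0 rose, 2 fell and 29 did not pass (7 fell when adjusted over the list alone, and 5 over all probe sets without the outlying array). Their median was -0.20, with a camera adjusted p of 0.00493 and an adjusted p of 0.85 with an estimated correlation. Of 21 NRF2 and antioxidant genes, 1 rose at 30 min, 0 fell and 20 did not pass (7 rose when adjusted over the list alone). Their median was 0.19, with a camera adjusted p of 0.000197 and an adjusted p of 0.85 with an estimated correlation. At 60 min, 2 of these rose, 0 fell and 19 did not pass (10 rose when adjusted over the list alone). Their median was 0.21, with a camera adjusted p of 0.00475, which passed the threshold neither on the deposited scale nor with median centring, and an adjusted p of 0.869 with an estimated correlation. Of 21 heat shock proteins and co-chaperones at 60 min, 4 rose, 0 fell and 17 did not pass (5 rose when adjusted over the list alone). Their median was 0.10, with a camera adjusted p of 0.0485, or 0.0514 without the outlying array and over the threshold on the deposited scale and with median centring, and an adjusted p of 0.869 with an estimated correlation.

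Between the arms, 99 probe sets passed at 30 min, 58 higher and 41 lower, and 1002 at 60 min, 584 higher and 418 lower. Without the preparation block the counts were 52 and 584. The 30 min count was 192 without the outlying array and 166 without the pair out of place at 120 min. It was 227 and 223 without the 30 min ischemia arrays of duplicate 1 (preparations 1 and 2), and 180 and 155 without the ischemia+reperfusion arrays of duplicate 1. On the deposited scale, where the median change lay at 0.18 and 0.21, 66 probe sets were higher and 9 lower at 30 min, and 2095 higher and 81 lower at 60 min. With median centring, 505 were higher and 1163 lower at 60 min.

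At 10 min, no gene separated the arms past the threshold: 0 probe sets passed in limma, against 1860 at an unadjusted p under 0.05. The NRF2 and antioxidant genes had a median of 0.13, with 0 of 21 past the threshold (1 rose when adjusted over the list alone), a camera adjusted p of 0.00159 and an adjusted p of 0.959 with an estimated correlation. Without the ischemia+reperfusion array that lay with 0 min, 1 probe set passed, that of Ddit4, a gene chosen here after its values were seen.

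At 120 min, the labelled groups did not separate the arms, and removal of the pair of arrays out of place did. As labelled, 0 probe sets passed in limma, against 1333 at an unadjusted p under 0.05, and the smallest adjusted p was 0.146. Hspa1a differed by 1.62 ± 0.59 (adjusted p = 0.62), its co-chaperone Dnajb1 by 0.59 (adjusted p = 0.62), Nr4a1 by -0.91 (adjusted p = 0.41) and Cxcl2 by -0.62 (adjusted p = 0.66). Of 9 endothelial markers, 0 passed (also when adjusted over the list alone). Their median was -0.18, with a camera adjusted p of 0.013, or 0.0692 without the block and 0.334 without the pair of arrays, and an adjusted p of 0.851 with an estimated correlation. Leaving out single arrays gave 103 calls (ischemia+reperfusion, preparation 2, duplicate 1), 1 (ischemia+reperfusion, preparation 2, duplicate 2) and 1 (ischemia, preparation 2, duplicate 1).

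Without the pair of arrays, 669 probe sets passed at 120 min, 408 higher and 261 lower with reperfusion (451 genes), and 3840 had an unadjusted p under 0.05. Hspa1a was then higher by 3.17 ± 0.18 (adjusted p = 1e-05), Dnajb1 by 1.14 ± 0.07 (adjusted p = 1e-05), the heat-inducible zinc finger gene Zfand2a by 2.02 ± 0.16 (adjusted p = 0.00012) and the transcription factor Klf5 by 1.53 ± 0.13. Cxcl2 was lower (-1.25 ± 0.28, adjusted p = 0.036), as was Ddit4 (-1.11, adjusted p = 0.038). Of the 21 heat shock proteins and co-chaperones, 6 rose and 0 fell (6 rose when adjusted over the list alone), with a camera adjusted p of 4.77e-05 and an adjusted p of 0.0591 with an estimated correlation. The pair was chosen from its values, and leaving out arrays for lying with the other arm favours a difference between the arms, so these p-values are not those of a planned test.

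A change with duration that differed between the arms was tested by the interaction. At 120 min, 0 probe sets passed in limma, against 1944 at an unadjusted p under 0.05, and 123 passed (87 higher, 36 lower) without the pair of arrays out of place. The sterol genes had a median interaction of -0.39 at 120 min, with 0 of 19 past the threshold over all probe sets (6 lower when adjusted over the list alone), a camera adjusted p of 3.36e-08 and an adjusted p of 0.664 with an estimated correlation. This list already had a higher median in ischemia+reperfusion at 0 min, which enters the interaction. Without the pair of arrays, its median interaction was -0.46, while its median difference between the arms at 120 min was -0.11. The heat shock list had a median interaction of 0.09, a camera adjusted p of 0.16 and an adjusted p of 0.904 with an estimated correlation. Without the pair of arrays, 2 of its 21 members passed at 120 min (7 when adjusted over the list alone). The list's camera adjusted p with an estimated correlation was then 0.0305 at 120 min and 0.0247 at 60 min. The same reservation about the choice of the pair holds. As labelled, 0 probe sets passed in the interaction at 10, 30 or 60 min, with smallest adjusted p-values of 0.055, 0.125 and 0.101 in limma. The pair is outside the 60 min interaction: Hspa1a stayed at 3.74 there without it, while its adjusted p in limma went from 0.24 to 2e-04. Over the 4 interaction terms together, 1 probe set passed, that of Gpr12, an orphan receptor coupled to G proteins (adjusted p = 0.011), against 2100 at an unadjusted p under 0.05. That count was 2 without the preparation block, 6 without the outlying array and 62 without the pair of arrays at 120 min. Leaving out single arrays moved it by over 1.5 times for 28 of the 40, from 0 without an array of 60 min ischemia to 8 without the 30 min ischemia array of preparation 2, duplicate 1. At 120 min, the count became 7 without the 120 min ischemia+reperfusion array of preparation 2, duplicate 1, 2 without the 0 min one of preparation 2, duplicate 2, and 1 without either 0 min ischemia array of preparation 2 or the 120 min one of preparation 1, duplicate 2.

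Of the panel followed through all groups, Ddit3, a stress-induced transcription factor, was not called in any comparison with 0 min. Nppb, a natriuretic peptide, and Myh6, the alpha myosin heavy chain, lay near the top of the intensity range, where a change may go unseen, and no stability is read from them. Vegfa rose in both arms at 120 min, by 0.73 ± 0.16 in ischemia and 0.84 ± 0.16 in ischemia+reperfusion.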

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

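The tests of the 3 arrays out of place, of steady growth with duration and of an unlabelled batch were chosen after the results were seen; the others were chosen before. Array measures and panel genes in the 10 groups gave 120 sets of 4 values, and 12 sets held a value far from the rest. Independent values would give about 1 in 20 sets. The sets share arrays, some arrays were flagged in several sets, and the 4 arrays of a group are duplicates of 2 preparations. The count therefore cannot be set against that rate.

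At 120 min, Hspa1a was 13.15 in the ischemia array of preparation 2, duplicate 2 (others 9.62 to 10.19) and 9.75 in the ischemia+reperfusion array of preparation 2, duplicate 1 (others 13 to 13.25), and Atf3 was 12.20 (others 11.11 to 11.14) and 10.69 (others 11.84 to 12.04) in the same arrays; the latter array also had a low median correlation, 0.965. Errors at single probe sets were not excluded. Other probe sets of the same genes followed by a median of 0.38 of the deviation (111 pairs, quartiles 0.08 and 0.76). That value lay between the limits for and against such errors. The rule that counted it against them, because both arrays scored with the other arm, was written after the results were seen. For calls over 1 log2 unit at 120 min of ischemia+reperfusion, the same measure was 0.76 (26 pairs). An exchange of labels or RNA between these arrays is a candidate explanation. Scores were taken over the 1002 probe sets called between the arms at 60 min, a difference between groups without 120 min arrays. The 120 min arrays still entered the variance estimate behind these calls, which numbered 1100 in limma without the pair. Over the 1002, the ischemia array scored 0.11, within the other ischemia+reperfusion arrays (0.05 to 0.15). The ischemia+reperfusion array scored -0.10, within the other ischemia arrays (-0.15 to -0.09). Over the 99 probe sets called between the arms at 30 min, the ischemia array scored 0.13, within the other ischemia+reperfusion arrays (0.03 to 0.15). There the ischemia+reperfusion array scored -0.19, below the other ischemia arrays (-0.12 to 0). The 10 min ischemia+reperfusion array of preparation 2, duplicate 1, scored -0.09 over the 368 probe sets called at 10 min of ischemia, within the 0 min arrays of its arm (-0.12 to -0.02) and below the others of its group (0.10 to 0.17), so a wrong label or RNA of a 0 min culture may account for it, while an exchange with a 0 min array of its arm is argued against, since the highest of those scored -0.02. A biological difference between dishes, such as uneven exposure, was not tested and stays open. For the 30 min ischemia+reperfusion array of preparation 2, duplicate 1, which correlated with the 60 min group of its arm by 0.22 and with its own by 0.07, no explanation was tested.

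The 0 min ischemia array of preparation 1, duplicate 1, had a median correlation of 0.872 with the other arrays (others of its group 0.969 to 0.976) and lay over 2 log2 units from its group at 507 of 12359 probe sets. Different RNA or a swapped label is argued against, because other probe sets of the same genes deviated by a median of -0.04 of the deviation of the probe set itself (372 pairs). The same value is what signal errors at single probe sets predict, so they remain a candidate explanation. Only 32.5% of the pairs shared a sign, however, with quartiles of -0.6 and 0.02. Many pairs thus deviated in opposite directions, and the cause of that was not tested. Myh6 was 12.07 in that array (others 13.38 to 13.52). No biological explanation was tested.

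Over the 2408 probe sets called at 120 min of ischemia, the median share of the change reached was 0.53 at 10 min, 0.34 at 30 min and 0.39 at 60 min, so 10 min lay nearer to 120 min than the times between. Differences at single probe sets could not be excluded: 74.3% of 261 pairs of probe sets of the same gene shared a sign at 10 min, under the 75% set in advance, and 80.7% of 176 pairs did without the outlying array. At 120 against 0 min, 71.2% of 1442 such pairs shared a sign in ischemia, also under 75%, and 87.3% of 763 in ischemia+reperfusion. The share was 76.1% of 452 pairs between the arms at 60 min, and 90.1% of 394 at 60 against 0 min of ischemia+reperfusion. A change that grows steadily with duration could not be excluded, because the excess at 10 over 60 min was 0.14 in all but 0.20 in preparation 1 and 0.08 in preparation 2. An unlabelled batch of arrays or RNA cannot be told apart from the groups, which each hold a single duration: 47 probe sets were called between 10 and 30 min of ischemia and 0 between 30 and 60 min in limma. Against 0 min, 18 and 24 were called at 30 and 60 min and 368 at 10 min, while 130 were called between 10 and 120 min. Between the arms, 0 were called at 10 and 120 min, and 99 and 1002 at 30 and 60 min. A batch holding 0, 30 and 60 min of ischemia would also enter the comparisons of the arms at 0, 30 and 60 min. It would enter those of 10 and 120 with 0 min of ischemia as well, and the interactions at 10 and 120 min. A biological early response that recedes and returns is also open and was not tested.

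The 0 min ischemia+reperfusion array of preparation 2, duplicate 2, had a median correlation of 0.96 (others 0.973 or above) and a log2 value of 13.32 for Nppb (others 13.50 to 13.52). Fos was 8.15 in the 0 min ischemia array of preparation 2, duplicate 2 (others 8.62 to 8.70), and 8.58 in the 0 min ischemia+reperfusion array of preparation 2, duplicate 1 (others 8.79 to 8.83). Vegfa was 12.19 in the 10 min ischemia array of preparation 1, duplicate 2 (others 12.40 to 12.43). Gpr12 changed with duration differently in the arms by the moderated F test (adjusted p = 0.011), with means of 6.49, 7.03, 6.33, 5.93 and 6.82 in ischemia and 6.79, 6.64, 6.88, 6.91 and 6.86 in ischemia+reperfusion from 0 to 120 min.

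Other splits of the same arrays, each array taken as a sample, were counted for each comparison. The preparation pairs the arrays, and only 18 of the 35 splits of a comparison hold both preparations equally, too few for a share under 0.05, so the limit of 5% set in advance for the 35 was not applied. All of these counts take duplicates as independent; if they are repeat arrays of the same RNA, splits that part them cannot be set against the labelled one. Against 0 min, ischemia gave 1688 calls at 10 min (highest other split 4), 490 at 30 min (25), 490 at 60 min (129) and 4217 at 120 min (1222). Ischemia+reperfusion gave 463 (363), 958 (8), 2664 (275) and 2906 (635) at the same times. Between the arms, 758 (58), 156 (1), 987 (4) and 2810 (99) were called at 0, 10, 30 and 60 min. At 120 min between the arms, 11 were called as labelled and 2281 in the highest other split, and 7 of 35 splits gave as many (4 of the 18). The counts do not show which arrays that split exchanges, but so many calls point to a structure of the samples that the labels do not carry. For the 120 min interaction, 112 calls against a highest other of 944 were found (11 of 100 splits, or 19 of 100 drawn within the preparations, where the highest other was 3045). Over the interaction terms together, 497 calls against a highest other of 46 were found (1 of 100, and 1 of 100 within the preparations, where the highest other was 2), while the fit on preparations gave 1 call in limma.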

How the results depend on the processing

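Removal of the outlying array, of the pair of arrays out of place at 120 min and of the array out of place at 10 min, and the comparison of 120 with 10 min of ischemia, were chosen after the results were seen, and the other alternatives were planned. Counts of calls are from limma throughout. The 213 calls of named genes kept their sign wherever they were tested. They were chosen among calls with the same sign in both preparations, so the fits of each preparation alone could not reverse them. With the stricter filter 136 of them were tested, with 1 probe set per gene 173, with a pseudocount of 1 205 and with a pseudocount of 64 212. Of the 213, 133 stayed past the threshold without the preparation block, 135 on the deposited scale, 192 with median centring and 180 without the outlying array. Of 82 list calls by camera, 73 stayed past the threshold without the block, 73 on the deposited scale, 71 with median centring and 0 with an estimated correlation, and 39 passed in fry. A single list changed direction in 1 comparison, fatty acid oxidation and PPAR target genes, reperfusion at 120 min: ischemia+reperfusion 120 min vs ischemia 120 min. Its median was 0.05, with a camera adjusted p of 0.0458, or 0.851 with an estimated correlation. That list turned downward within preparation 1 (adjusted p = 0.658) and without the 120 min ischemia value of preparation 2 (adjusted p = 0.532). Its adjusted p ran from 4.44e-05 to 0.918 as single arrays or preparations were left out, and the cause was not tested. Signal over background limits dim genes, since 15.8% of deposited values were negative. A lone preparation in a group was assumed to vary like the other groups.

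Without the preparation block, which uses the pairing of groups by preparation, 176 probe sets passed at 10 min, 14 at 60 min and 1484 at 120 min of ischemia. In ischemia+reperfusion 2, 56, 411 and 645 passed at 10, 30, 60 and 120 min. Between the arms 16, 52 and 584 passed at 0, 30 and 60 min, and 2 over the interaction terms together. The block changed no other count by more than 1.5 times.

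With duplicates as separate samples, 1688, 490, 490 and 4217 probe sets passed at 10, 30, 60 and 120 min of ischemia. In ischemia+reperfusion 463, 958, 2664 and 2906 passed at these times. Between the arms 758, 156, 987, 2810 and 11 passed at 0, 10, 30, 60 and 120 min, with 112 for the 120 min interaction and 497 over the interaction terms together. These counts treat duplicates as independent, which the labels do not establish. With a duplicate correlation in that fit, 1183, 285 and 295 passed at 10, 30 and 60 min of ischemia. In ischemia+reperfusion 348, 709, 2180 and 2467 passed at 10, 30, 60 and 120 min. Between the arms 483, 72, 679, 2239 and 1 passed at 0, 10, 30, 60 and 120 min, with 50 and 209 for the interactions.

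Without a filter, 35 probe sets passed at 30 min of ischemia and 23 at 10 min of ischemia+reperfusion. Between the arms 107, 5 and 19 passed at 0, 10 and 120 min, with 25 for the 120 min interaction and 22 over the interaction terms. With the stricter filter, 58 passed at 10 min of ischemia+reperfusion and 2 over the interaction terms. With a pseudocount of 64, 46 passed at 10 min of ischemia+reperfusion, 163 between the arms at 30 min, 1 for the 120 min interaction and 3 over the interaction terms. A pseudocount of 1 moved no count by more than 1.5 times. With 1 probe set per gene, which tests fewer items, 233, 30 and 1170 genes passed at 10, 30 and 120 min of ischemia and 37 and 678 at 10 and 120 min of ischemia+reperfusion. In that setting 20 and 626 passed between the arms at 0 and 60 min, with 6 and 4 for the interactions.

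On the deposited scale, 66 and 3 probe sets passed at 10 and 60 min of ischemia. In ischemia+reperfusion 29, 65, 157 and 305 passed at 10, 30, 60 and 120 min. Between the arms 17, 2176 and 1 passed at 0, 60 and 120 min, with 1 for the 120 min interaction and 0 over the interaction terms in limma, where 2100 had an unadjusted p under 0.05 after normalization. With median centring, 3 passed at 10 min of ischemia+reperfusion, 1668 between the arms at 60 min and 1 for the 120 min interaction. The cause of these moves was not tested beyond the shift of the medians.

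Within preparation 1, where only the spread between duplicates enters, 120, 45 and 63 probe sets passed at 10, 30 and 60 min of ischemia and 433 at 10 min of ischemia+reperfusion. Between its arms 382, 45, 510 and 621 passed at 0, 10, 30 and 120 min, with 245 and 188 for the interactions. Within preparation 2, 225, 38, 14 and 1089 passed at 10, 30, 60 and 120 min of ischemia. In ischemia+reperfusion 0, 281 and 465 passed at 10, 30 and 120 min, and between the arms 13, 37, 450 and 1 at 0, 30, 60 and 120 min, with 2 and 6 for the interactions. Preparation 2 holds the 4 arrays that lie nearer to another group by over 0.1.

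Without the outlying array, 2 probe sets passed at 30 min of ischemia and 1 at 10 min of ischemia+reperfusion. Between the arms 157 and 192 passed at 0 and 30 min, and 6 over the interaction terms. Without the pair of arrays out of place at 120 min, 7 passed at 30 min of ischemia and 11 at 10 min of ischemia+reperfusion. Between the arms 35, 1, 166 and 669 then passed at 0, 10, 30 and 120 min, with 123 and 62 for the interactions. Without the array out of place at 10 min, 29 passed at 30 min of ischemia, 348 at 10 min of ischemia+reperfusion, 1 between the arms at 10 min, and 2 and 3 for the interactions. Against 10 min in place of 0 min, 130 passed at 120 min of ischemia.

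Leaving out each preparation of a compared group, or each array, in turn gave 1 to 1870 probe sets at 10 min of ischemia, 2 to 1570 at 30 min, 1 to 1610 at 60 min and 318 to 3197 at 120 min. In ischemia+reperfusion the ranges were 0 to 348, 0 to 215, 6 to 1420 and 97 to 1763. Between the arms they were 0 to 1840 at 0 min, 0 to 1 at 10 min, 5 to 227 at 30 min, 32 to 1254 at 60 min and 0 to 103 at 120 min. They were 0 to 1381 for the 120 min interaction and 0 to 1357 over the interaction terms. The highest counts at 10, 30 and 60 min of ischemia, between the arms at 0 min and for the interactions came without the 0 min ischemia value of preparation 2. That fit left 0 min of ischemia with preparation 1 alone, an average that includes the outlying array, so those counts rest in part on it. Of 656 list calls with 1 array left out, 583 stayed past the threshold, and of 328 with 1 preparation left out, 251 did. Of 1704 named gene calls with 1 array left out, 1504 stayed past the threshold, and of 852 with 1 preparation left out, 374 did. Within preparation 1, 136 of the 213 named gene calls stayed past it, and within preparation 2, 103 did.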

Other observations

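In the ischemia+reperfusion arm, some clock genes rose and some cell cycle genes fell at 120 min, and neither list passed with an estimated correlation. Per2, a period gene of the circadian clock, rose by 1.11 ± 0.18 log2 units (adjusted p = 0.01, or 0.087 without the preparation block) and Cry2, a cryptochrome repressor of the clock, by 0.66 ± 0.14 (adjusted p = 0.023). Of 16 clock genes, 5 rose, 0 fell and 11 did not pass (6 rose and 1 fell when adjusted over the list alone), with a median of 0.32, a camera adjusted p of 0.0026 and an adjusted p of 0.231 with an estimated correlation. Aurka, a kinase of the mitotic spindle, fell by 0.67 ± 0.14 (adjusted p = 0.02) and Ccnb1, a mitotic cyclin, by 0.59 ± 0.12 (adjusted p = 0.019). Kif2c, a kinesin outside the cell cycle list, fell by 1.20 ± 0.15 (adjusted p = 0.0035). Of 27 cell cycle genes, 0 rose, 3 fell and 24 did not pass (6 fell when adjusted over the list alone), with a median of -0.21, a camera adjusted p of 0.000509 and an adjusted p of 0.382 with an estimated correlation. In ischemia alone at 120 min, the repressor Nfil3, also a member of the clock list, rose by 0.90 ± 0.14 (adjusted p = 0.0055).

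At 120 min, Angptl4, an inhibitor of lipoprotein lipase, rose by 1.27 ± 0.18 in ischemia and 1.61 ± 0.18 in ischemia+reperfusion. Gdf15, a stress-induced cytokine, rose by 1.40 ± 0.28 in ischemia (adjusted p = 0.012, or 0.082 without the preparation block). Xiap, an inhibitor of caspases, fell by 0.80 ± 0.08 in ischemia and by 0.33 ± 0.08 in ischemia+reperfusion (adjusted p = 0.04, or 0.052 without the block), and Xirp1, a protein of the intercalated disc, rose by 0.67 ± 0.09 and 0.78 ± 0.09. The comparison of 120 with 10 min of ischemia was chosen after the results were seen. Against 10 min in place of 0 min of ischemia, 130 probe sets passed at 120 min, 68 higher and 62 lower, of which 114 were also called against 0 min. Fos (2.29 ± 0.20), Cxcl2 (2.21 ± 0.24) and Nr4a1 (2.17 ± 0.19) were among those higher at 120 than at 10 min. Of 31 immediate early genes, 6 rose and 0 fell, with a median of 0.43. Of 32 HIF targets, 2 rose and 0 fell, with a median of -0.04 and a camera adjusted p of 0.808. Vegfa (0.02 ± 0.16, adjusted p = 0.96 in limma) and Hmox1 (0.77 ± 0.32, adjusted p = 0.24) did not pass.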
